A study of Mus musculus with 28 samples.

How the data were processed

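Transcripts were measured in wells of sorted cells from livers of C57BL/6 male mice, dissociated by collagenase perfusion per the labels' protocols. There were 2 kinds of samples: single non-parenchymal cells (2 mice, 11 libraries) and hepatocytes sorted together with an attached CD31+ cell (3 mice, 17 libraries). Libraries were made with MARS-seq from the 3' end of each mRNA, per the labels' protocols. Base calls were converted with bcl2fastq 2.15.0.4 and the genome build was mm9, per the submitters' processing notes. The aligner and the gene annotation are not given in the sources used here.

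The deposited tables hold counts: whole numbers of UMIs per gene symbol and well, with no normalization by the authors, and 92 rows of ERCC spike-in RNA. Spike-in UMIs were 52.8% of all UMIs in the single-cell table and 0.715% in the pair table, and they were left out. Gene UMIs totalled 2660172 and 56976156. The wells carry no map to library or mouse, so each table was treated as 1 sample. The edgeR test with TMM factors and mouse as a block and the camera and fry list tests, planned before the data were examined, were therefore replaced by levels with intervals, as the plan provided for this case. No paired analysis was possible because no source maps wells to mice, so the zones of each mouse could not be separated. Gene lists, landmarks, markers, filters and most alternatives were fixed before the data were examined.

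Pairs needed at least 1000 UMIs and at least 20 UMIs of 25 hepatocyte landmark genes, 13 pericentral (such as Glul and Cyp2e1) and 12 periportal (such as Cyp2f2 and Hal). That kept 4612 pairs and left out 9. The score of a pair set its pericentral landmark UMIs against its periportal ones, each divided by their mean over pairs. The outer tertiles, above a score of 0.781 and up to 0.299, were the pericentral and periportal zones, and 913 pairs lay within 0.05 of a limit. Landmark genes were left out of all comparisons. The median kept pair held 161 landmark UMIs, and the median pair had 10830.5 UMIs in the pericentral and 10139 in the periportal zone.

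A gene was counted as endothelial if it reached at least 10 UMIs per 1000000 in endothelial-like single cells, was at least as high there as in every other named non-parenchymal class, and had at least 50% of its level in pairs accounted for by endothelial RNA. The endothelial share of pair UMIs was set at 2.35%, the median over 20 markers of the level in pairs divided by that in endothelial-like cells. Because single cells came from older mice, that share carries any difference between the ages. UMIs were summed over the pairs of a zone. Levels are per 1000000 UMIs of the 697 endothelial genes for endothelial genes and per 1000000 of all gene UMIs for other genes, with at least 30 UMIs over both zones. Levels have exact Poisson intervals and ratios exact conditional binomial intervals, at 95%. Where 1 zone held 0 UMIs, the fold was taken against a floor of 3 counts over the zone and is a lower bound.

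Named genes were the 10 largest folds in each direction among genes with at least 100 UMIs over both zones and separate Poisson intervals. Examples per fixed list were to be the members with the smallest p-values, and without a test the size of the fold replaced p. Genes named in single endothelial cells were those named from the pairs. Lists are summarised by their median log2 ratio, with the percentile among the medians of 10000 random lists matched on expression, which describes these libraries and is no test. Symbols equal but for letter case were left out (68), and 456 of 459 list genes were found, 5 by an older symbol.

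As batches, pair wells were split into 17 blocks of well numbers, each the size of a plate, and zones were also taken within blocks. Block numbers 1 to 16 and 41 equal the numbers in the library titles, but no source states that blocks are libraries, so blocks were not joined into mice. A gene's direction was read in blocks with at least 10 of its UMIs.

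Single cells needed at least 300 UMIs, which kept 2692 wells and left out 1028. Counts were scaled to a total of 1000, log-transformed and reduced to 30 principal components of 2000 variable genes, and clustered with Leiden on 15 neighbours at resolution 1.0. A cluster took the name of a marker list if at least 3 of its markers were 2-fold higher in it. No doublet caller was run, since cells were sorted into wells of plates. Endothelial-like cells were scored by endothelial landmark genes that are partly known from the study of these samples, and the outer tertiles were compared without those genes.

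The comparison of endothelial genes was run on simulated Poisson counts, with the observed score as the true position and no differences between mice or blocks. The direction was right for 98.0% of genes with a simulated fold of 1.5 and 100% with folds of 2.0 and 4.0, and the interval excluded 0 for 60.8%, 81.0% and 98.1%. Among unchanged genes 2.99% of intervals excluded 0, and 97.3% of all intervals held the expected value. Such coverage follows from the Poisson setting and does not show that the intervals cover differences between mice or blocks.

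Alternatives changed the normalization (median-of-ratios size factors as in DESeq2, computed without a fit, and all genes as the library size), the filter on low counts, the depth per pair, the landmark lists and score, the zone limits, the endothelial rule, the clustering, and the pairs with Kupffer cell markers. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and igraph 0.11.9, and matplotlib 3.10.9 for plots.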

Results

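Transcripts of mouse liver were counted with MARS-seq, a plate-based method that tags each captured mRNA molecule at its 3' end with a unique molecular identifier (UMI). One table held 3720 wells of single non-parenchymal cells, from 11 libraries of 2 C57BL/6 male mice aged 3 and 4 months. The other held 4621 wells, each with a hepatocyte and an attached CD31+ cell sorted together as a pair, from 17 libraries of 3 mice aged 6 or 7 weeks. The median well held 526 gene UMIs among single cells, with a range of 60 to 5531. Among pairs the median was 10450, with a range of 2423 to 49311. Well names carried no map to library or mouse, so each table was treated as 1 sample. No difference was tested across mice, and no p-value was computed. All intervals are 95% intervals and cover counting error only.

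The pairs address where along the liver lobule, the unit of tissue between a central vein and the portal triads, endothelial genes are expressed. The hepatocyte of each pair gave its position through landmark genes, and the endothelial genes were then compared between the pericentral zone (1536 pairs) and the periportal zone (1538 pairs), the outer tertiles of the landmark score. Rspo3, an R-spondin that potentiates Wnt signalling, was 8.13-fold higher in the pericentral zone, with 122 UMIs against 17 (log2 ratio 3.02, interval 2.29 to 3.85). Cdh13, which encodes T-cadherin, was 6.27-fold higher there (log2 ratio 2.65, interval 2.18 to 3.15). Thbd, the thrombin receptor thrombomodulin, was 3.33-fold higher and the fatty acid binding protein gene Fabp4 3.20-fold higher. The Wnt ligand gene Wnt2 was 2.61-fold higher, with 269 UMIs against 117. In the periportal zone, Flrt1 was 3.73-fold higher (log2 ratio -1.90, interval -2.56 to -1.28), and Ltbp4, which encodes a latent TGF-beta binding protein, 2.84-fold higher (log2 ratio -1.51, interval -1.77 to -1.25). The Notch ligand gene Dll4 was 2.82-fold higher there, with 83 UMIs against 26, and the netrin gene Ntn4 2.72-fold higher.

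The pericentral genes with the largest folds also included Ier3 (log2 ratio 1.42), Olfm1 (1.12), Kit (0.98) and Gja4 (0.90). The other periportal genes were Adam23 (log2 ratio -1.30), Ldb2 (-1.03), Slc43a2 (-0.95), Lzts2 (-0.89), Itga9 (-0.89) and Hlx (-0.88). Levels of these genes are per 1000000 UMIs of the 697 genes counted as endothelial, of which 473 had at least 30 UMIs over both zones. The median log2 ratio of those 473 genes was -0.01, and the central 95% of them lay between -1.12 and 1.16. Rspo3, Cdh13, Thbd, Fabp4, Wnt2, Kit, Ltbp4, Dll4 and Ntn4 were already on landmark lists that rest on knowledge of this study, so their direction here is not independent evidence.

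Pair wells fell into 17 plate-sized blocks of well numbers that differed in score, with block medians from 0.429 to 0.80, and in depth. The blocks have the numbers 1 to 16 and 41, the same as in the titles of the 17 pair libraries, so they may be those libraries, but no source states this and no block was assigned to a mouse. With zones taken within each block, and counting blocks with at least 10 UMIs of the gene, Fabp4 had the pooled direction in 17 of 17 blocks, Wnt2 in 16 of 16, Ltbp4 in 16 of 16, Adam23 in 15 of 15, Cdh13 in 14 of 14 and Thbd in 14 of 14. Rspo3 reached that count in 6 blocks and was higher in the pericentral zone of all 6. Hlx had the pooled direction in 4 of 8 blocks and Lzts2 in 3 of 4.

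**Figure D1:**
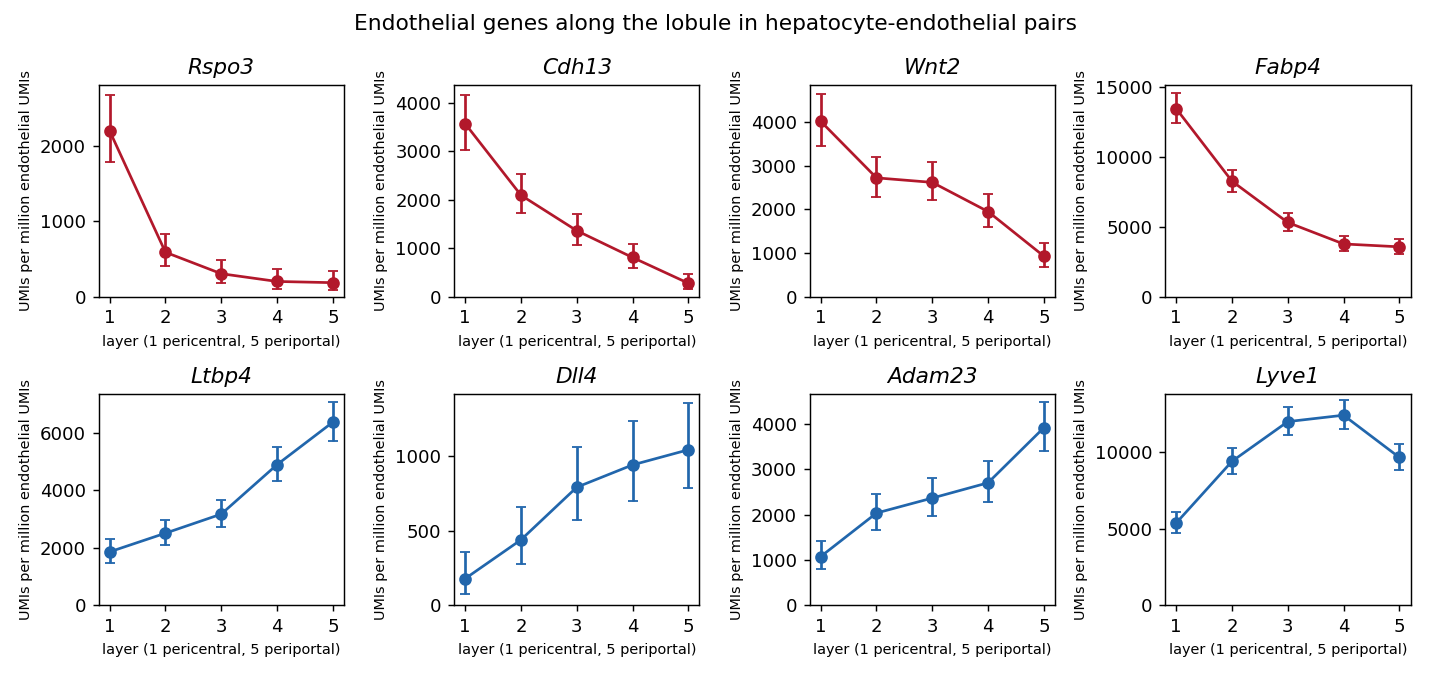
Levels of 8 endothelial genes (UMIs per 1000000 UMIs of endothelial genes, linear axis from 0) in 5 layers of pairs ordered by landmark score, from layer 1 (pericentral) to layer 5 (periportal); points are levels of UMIs summed over the pairs of a layer and bars are exact 95% Poisson intervals. The 4 genes in red have their highest level in layer 1, Ltbp4, Dll4 and Adam23 in layer 5, and Lyve1 in layer 4.

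Among the endothelial lists fixed before the data were examined, other than the landmark lists (medians 1.71 and -1.39), Wnt ligands and potentiators stood furthest from 0. All 4 measured members had a log2 ratio above 0, with a median of 1.46 (interval 1.05 to 1.93), and of 0.89 with pairs split at the median score. That median lay at percentile 100.0 of 10000 random lists matched on expression, as a description of these libraries. Rspo3 and Wnt2 are also on the landmark lists, so the median of this list is not independent evidence. Beside Rspo3 and Wnt2, the Wnt antagonist gene Dkk3 had a log2 ratio of 1.54 with 41 UMIs against 16, and Wls, which carries Wnt proteins to the cell surface, 0.33 (interval -0.27 to 0.93). Wnt9b fell outside the endothelial rule, with 37 UMIs in the pericentral zone and 0 in the periportal zone. Porcn, on the same list, also fell outside the rule and went the other way, with 21 UMIs against 41. Wnt4 (6 against 4), Wnt5a (6 against 7) and Rspo1 (0 in both zones) were outside it too. Of 9 measured Notch and ephrin genes 2 had a log2 ratio above 0, and the median was -0.16 (percentile 27.2), or -1.02 over genes with at least 80% of their level from endothelial cells. Dll4 (-1.49) and the ephrin gene Efnb2 (-1.33), both on the landmark lists, lay toward the portal side. The Notch ligand gene Jag1 (0.84) lay toward the central side with 41 UMIs against 26.

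The extracellular matrix list had a median of -0.26 (percentile 0.685), with 3 of 9 members above 0, and a median of 0.01 with each pair thinned to 1000 UMIs. Ltbp4 and Ntn4, both on the landmark lists, lay toward the portal side, and Bgn (0.45) and Timp3 (0.44) toward the central side. Of 8 scavenger and endocytic receptor genes 3 had a log2 ratio above 0 (median -0.03, percentile 37.9, and -0.28 with each pair thinned to 1000 UMIs). Lyve1, a hyaluronan receptor of sinusoidal endothelium, was 1.60-fold higher in the periportal zone with 970 UMIs against 536, and Fcgr2b had a log2 ratio of -0.29. Stab2 (0.26) went the other way. Some members of this list fell outside the endothelial rule. Among them Msr1, also on a landmark list, had 19 UMIs in the pericentral zone and 154 in the periportal zone, but Colec12 had 827 against 545. The haemostasis list had 3 measured members, all higher in the pericentral zone (median 0.48, percentile 98.2, and 0.18 with pairs split at the median score). Thbd, also on a landmark list, led, followed by Tfpi (0.48), which encodes an inhibitor of the tissue factor pathway. The VEGF, Tie and endoglin receptor genes had a median of 0.15 over 7 members (percentile 90.7), with values from Flt4 (-0.11) to Flt1 (0.23), and a median of -0.05 per 1000000 of all UMIs. The median was -0.05 for 5 angiocrine and BMP pathway genes (percentile 43.0) 0.17 with each pair thinned to 1000 UMIs, and -0.62 with an endothelial-like level at least 5 times the hepatocyte-like level, with Hgf at -1.36 on 10 UMIs against 29. The median was 0.00 for 5 shear stress genes (percentile 60.4). For 4 leukocyte adhesion and vascular identity genes it was -0.00 (percentile 50.6), but 0.50 with each pair thinned to 1000 UMIs and -0.30 under the same 5 times rule, so no direction is given. The 14 dissociation and immediate early genes, given per 1000000 of all UMIs since none met the endothelial rule, had a median of 0.11 (percentile 47.4), and -0.12 with each pair thinned to 1000 UMIs, with Egr1 (-1.67) and Fos (-1.28) toward the portal side and Atf3 (1.10) and Hspa1b (0.90) toward the central side.

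UMIs of endothelial genes made up 0.415% of all gene UMIs in the pericentral zone and 0.476% in the periportal zone. Per 1000000 of all UMIs, log2 ratios of endothelial genes would therefore be lower by 0.20.

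The same zones place hepatocyte genes. Slc13a3, a dicarboxylate transporter gene, had 246 UMIs in the pericentral zone and 1 in the periportal zone (log2 ratio 7.92, interval 5.43 to 13.23). Rcan2 had 149 against 2 UMIs (6.20), the thyroxine-binding globulin gene Serpina7 555 against 19 (4.85), and Pparg, a nuclear receptor of lipid metabolism, 530 against 22 (4.57). Aldh3a2, a fatty aldehyde dehydrogenase gene, was 22.7-fold higher in the pericentral zone, with 9455 UMIs against 411. Toward the portal side, Cib3 was 29.0-fold higher (372 UMIs against 13) and Sdsl, a serine dehydratase-like gene, 27.7-fold higher (464 against 17). Cryl1 was 25.4-fold higher there, and Ctnnbip1, an inhibitor of beta-catenin binding to TCF factors, 18.3-fold higher with 433 UMIs against 24.

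The other pericentral genes among the 10 with the largest folds were Cyp2c38 (log2 ratio 5.82), Gm13775 (4.70), 1700080G11Rik (4.68), Lhpp (4.54) and Tox (4.40). The other periportal genes were Gm4956 (-5.49), Tstd1 (-3.97), Slc3a1 (-3.93), Tff3 (-3.89), Nipal1 (-3.58) and Aqp4 (-3.53). Each of the 20 genes had the pooled direction in every block with at least 10 of its UMIs, which was 17 blocks for Aldh3a2, 16 for Cyp2c38 and 6 for Aqp4. Cyp2c38 belongs to a family of near-identical genes and Gm13775 and Gm4956 are predicted genes, so their counts could hold reads of related copies and are uncertain. Across the 10934 genes with at least 30 UMIs the median log2 ratio was 0.11, and values of single genes should be read relative to it.

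All 8 Wnt/beta-catenin target genes were higher in the pericentral zone, with a median log2 ratio of 2.49 (interval 2.12 to 2.69; percentile 100), and 1.47 over those with at least 100 UMIs. One of them, Nkd1 (0.65), also met the endothelial rule, with an estimated 66.1% of its level from endothelial RNA. The stem cell marker gene Lgr5 had 89 UMIs against 1 (6.46), and Sp5 had 43 against 0, which is at least 14.1-fold higher with a floor of 3 counts over the zone. Axin2, a feedback inhibitor of the pathway, was 8.53-fold higher and the transcription factor gene Tbx3 8.92-fold higher. Of 21 xenobiotic metabolism genes 19 were higher in the pericentral zone (median 0.80, percentile 100), with Cyp2c38 (5.82) and Cyp2c40 (3.90) at one end and Cyp3a13 (-0.33) and Ugt2b5 (-0.01) at the other. Members of the Cyp2c, Cyp2d, Cyp3a, Gstm and Ugt families share sequence, so their single values are uncertain. Of 13 bile acid genes 12 had a log2 ratio above 0 (median 0.42, percentile 99.9), but Abcb11 (0.01, interval -0.05 to 0.07) had that direction in 7 of 17 blocks and Akr1d1 (0.13) in 10 of 17. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, was 5.35-fold higher, and Hsd3b7 3.26-fold. Slc27a5 had a log2 ratio of -0.14.

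**Figure D2:**
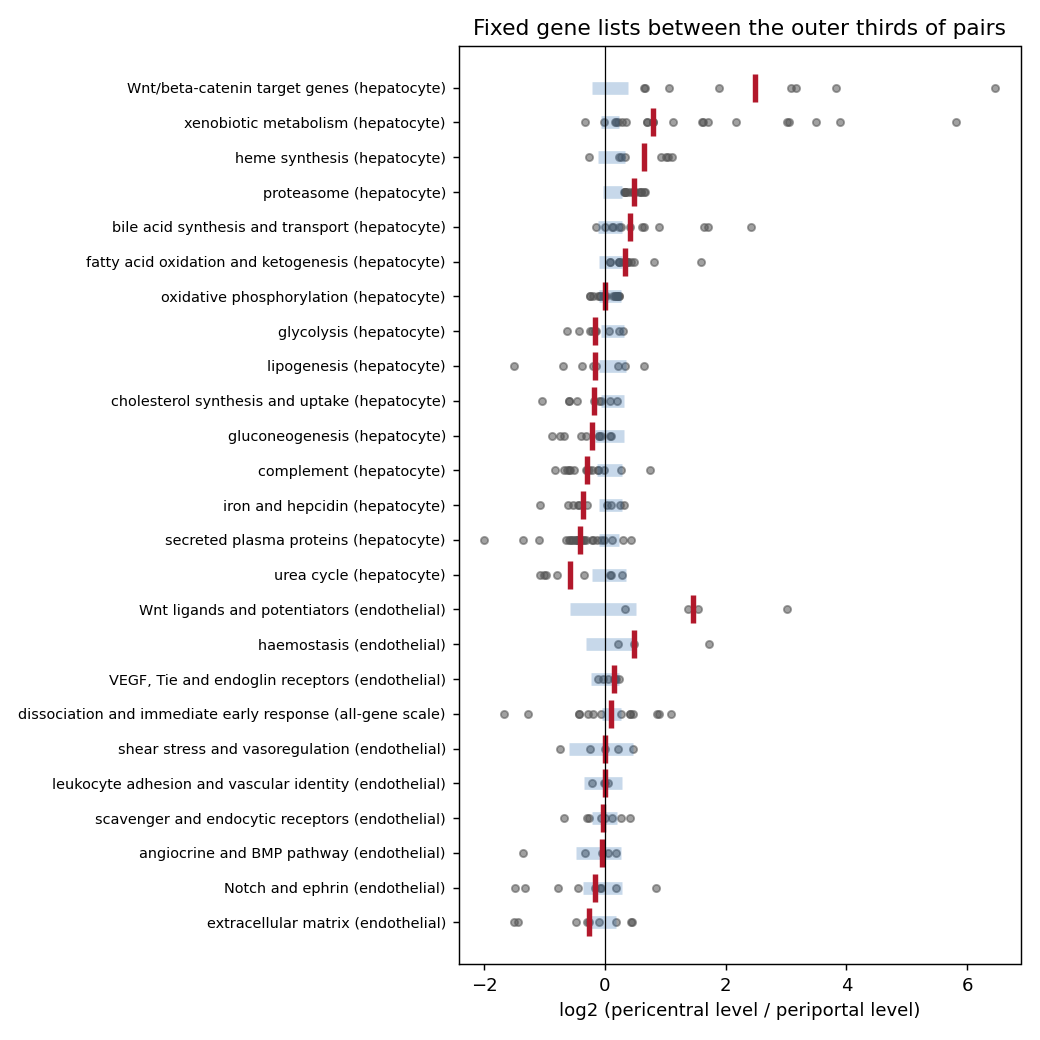
Log2 ratio of the pericentral to the periportal level (horizontal axis) of the members of each fixed hepatocyte and endothelial gene list, without the landmark and cell type lists, with 1 grey point per gene, a red bar at the list's median, and a blue band for the central 95% of the medians of 10000 random lists matched on expression. The Wnt/beta-catenin target genes (median 2.49) and the Wnt ligands and potentiators (median 1.46) lie furthest to the right of the lists shown, and the urea cycle genes (median -0.57) furthest to the left.

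Other hepatocyte lists with medians above 0 were heme synthesis (0.64, percentile 100.0), proteasome (0.48, percentile 100) and fatty acid oxidation and ketogenesis (0.33, percentile 99.1). All 14 proteasome genes were higher in the pericentral zone, from Psma2 (0.31) to Psmb5 (0.67). All 14 fatty acid oxidation genes had a log2 ratio above 0, up to Acaa1b (1.60), but Cpt1a and Hadha (0.09 each) lay below the median of all genes. Of 8 heme synthesis genes 7 were higher in the pericentral zone, with Alas1, which encodes the first enzyme of the pathway, at 1.12 and Ppox at -0.26 on 28 UMIs against 33. The 18 oxidative phosphorylation genes had a median of 0.01 (percentile 14.8), with 9 on each side and values from -0.25 for Sdhd to 0.24 for Atp5j. That median was -0.09 with size factors.

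Genes of the urea cycle, which turns ammonia into urea, had a median of -0.57 (percentile 0.0300). Asl was 2.11-fold higher in the periportal zone, Ass1 2.02-fold and Arg1 1.96-fold, while Slc25a13 (0.28) was higher in the pericentral zone. Nags had 0.10 (interval -0.04 to 0.23), and Slc25a15 0.09 with that direction in 7 of 17 blocks, both below the median of all genes. Of 25 secreted plasma protein genes 22 had a log2 ratio below 0 (median -0.41, percentile 0), but Rbp4 (-0.02) had that direction in 1 of 17 blocks and Ttr (-0.07) in 8 of 17. Albumin (Alb) was 2.13-fold higher there, Hpx 2.54-fold and Apoa4 4.0-fold, while Apoa2 (0.43), Apoe (0.30) and Apoh (0.12) were higher in the pericentral zone. Of 15 complement genes 2 were higher in the pericentral zone, C6 (0.74) and C4bp (0.27). The median was -0.30 (percentile 0.105), with C9 (-0.82) and Cfi (-0.68) furthest toward the portal side.

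Medians were -0.21 for gluconeogenesis (percentile 1.44), led by Fbp1 (-0.87) and Got1 (-0.75), and -0.16 for glycolysis (percentile 0.340), led by Gpi1 (-0.62) and Pklr (-0.42). With each pair thinned to 1000 UMIs these medians were -0.05 and -0.00. In the same lists Ldha (0.23) was higher in the pericentral zone, and Mdh2 (0.11) lay at the median of all genes. Lipogenesis had a median of -0.17 (percentile 0.580), and -0.09 with pairs thinned in that way, with Acly, which makes cytosolic acetyl-CoA, 2.85-fold higher in the periportal zone, Acaca at -0.70, and Me1 (0.64) and Thrsp (0.34) on the other side. Cholesterol synthesis and uptake had a median of -0.18 (percentile 0.180), and -0.07 with pairs thinned, with Sqle at -1.04, Idi1 at -0.60 and Fdft1 at 0.20. The iron and hepcidin list had a median of -0.36 (percentile 0.0100), and -0.17 with zones taken within blocks, with the BMP response gene Id1 at -1.07, Hamp, which encodes the iron hormone hepcidin, at -0.61, and Ftl1 (0.32) and Fth1 (0.25) on the other side.

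Markers of other cell types were compared between zones per 1000000 of all UMIs. The endothelial markers had a median log2 ratio of -0.18 over 20 genes. Kupffer cell markers had a median of -0.72 over 6 genes (interval -1.04 to -0.27), with Cd5l at 14 UMIs against 37 and C1qa at 9 against 24 but Fcna at 81 against 62 and C1qb at 32 against 29, and a median of 0.13 without pairs holding at least 2 UMIs of Kupffer cell markers other than Slc40a1. Among cholangiocyte markers Sox9 had 22 UMIs in the pericentral zone and 200 in the periportal zone, and Spp1 15 and 121. Their median was -3.03 over 3 genes, although Krt8 was higher in the pericentral zone (0.56) and other markers of the list were all but absent: Epcam had 0 and 1 UMIs, and Krt19 and Krt7 had 0 in both zones. Medians were -0.20 for 9 stellate cell or fibroblast markers (interval -0.49 to 0.01) and -0.20 for 3 plasma cell markers (interval -0.60 to 0.01), 0.32 for 6 cycling cell markers (percentile 89.1) and -0.44 for 11 hepatocyte markers. The remaining marker lists had at most 2 measured genes and were compared as summed UMIs, pericentral against periportal. There were 44 against 64 UMIs of monocyte or macrophage markers, 36 against 46 of dendritic cell markers, mostly Naaa, 46 against 24 of T cell markers, of which Themis alone had 32 against 2, 17 against 9 of B cell markers, mostly Vpreb3 and Ebf1, 3 against 7 of neutrophil markers and 1 against 3 of NK cell markers. Plasmacytoid dendritic cell markers had 3683 against 3681 UMIs, mostly Bst2, erythroid markers 2146 against 1934, mostly Alas2, and basophil or mast cell markers 19 against 44, all Gata2.

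The endothelial-like single cells, from other mice, allow the zonation of endothelial genes to be compared with the pairs. Adam23 had a log2 ratio of -1.34 (interval -1.78 to -0.91) between cells scored pericentral and cells scored periportal, beside -1.30 in pairs. Olfm1 had 1.94 (interval 1.16 to 2.81) beside 1.12, and Lyve1 -0.80 (interval -1.01 to -0.58) beside -0.68. Itga9 (-0.82), Ldb2 (-0.69) and Gja4 (0.48) also had the sign of the pairs with intervals that exclude 0. Ier3 (0.56), Flrt1 (-0.53), Slc43a2 (-0.51) and Hlx (-0.37) had the sign of the pairs with intervals that include 0. Of the genes whose intervals exclude 0 in both data sets, 3 had opposite signs: Fcgr2b with 0.24 (interval 0.02 to 0.47) beside -0.29, Calcrl with -0.51 (interval -1.0 to -0.03) beside 0.34, and Prex2, which exchanges nucleotides on the GTPase Rac, with -0.85 (interval -1.52 to -0.20) beside 0.47. These 3 were singled out after their values were seen.

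Of the 296 genes compared, 183 (61.8%) had the same sign in both data sets, and across these genes Pearson's r was 0.35 and Spearman's rho 0.33. Among the 91 genes whose interval in pairs excludes 0, 68 (74.7%) had the same sign. Genes are not independent replicates, so no p-value was computed. The comparison set 259 cells against 255, and 105 of the 847 endothelial-like cells held no UMI of the scoring genes. The same-sign share was 62.5% in the lower and 67.2% in the upper range of well numbers.

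**Figure D3:**
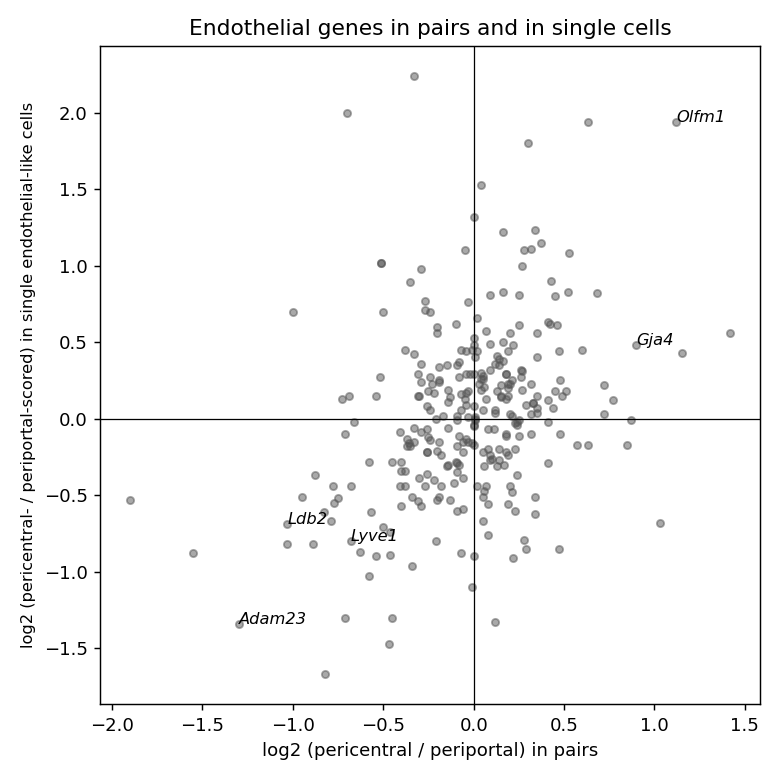
Log2 ratio of 296 endothelial genes between pericentral-scored and periportal-scored single endothelial-like cells (vertical axis) against the log2 ratio between the pericentral and periportal zones of pairs (horizontal axis), 1 point per gene. Adam23, Lyve1 and Ldb2 lie at negative values on both axes and Olfm1 and Gja4 at positive values on both, and 61.8% of the genes have the same sign on both.

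Among the 2692 single cells with at least 300 UMIs, endothelial-like cells were the largest class with 847 cells, 31.5% (interval 29.7 to 33.3, exact Clopper-Pearson). With at least 600 UMIs per cell T cell-like cells were the largest, with 28.0% against 24.0%. Endothelial-like cells carried Ptprb, Clec4g, Kdr and Lyve1, and Clec4g, a C-type lectin of sinusoidal endothelium, had a UMI in 80.6% of them and in 5.53% of T cell-like cells, at median depths of 573 and 825 UMIs. T cell-like cells made up 24.9% (interval 23.2 to 26.5), with Bcl11b, Cd3g and Il7r. Kupffer cell-like cells made up 10.9% (interval 9.73 to 12.1), and the Kupffer cell lectin Clec4f had a UMI in 83.3% of them and in 4.25% of endothelial-like cells, at median depths of 887 and 573 UMIs. B cell-like cells (10.4%) carried Cd79b and Ms4a1, and NK cell-like cells (8.99%) the granzyme genes Gzma and Gzmb. Cd3e, on the fixed T cell list, had a UMI in 24.8% of NK cell-like and 39.2% of T cell-like cells. Median depths were 706 and 825 UMIs, and T cells within the NK cell-like class were not excluded. Dendritic cell-like cells (5.42%) carried Xcr1 and Naaa, and plasmacytoid dendritic cell-like cells (4.09%) Siglech. Neutrophil-like cells (1.11%) carried S100a8 and S100a9. A hepatocyte-like class (2.12%, 57 cells) had Bhmt and Arg1 among its 10 top genes. None of the fixed hepatocyte markers was among those 10, but all 13 were at least 2-fold higher in this class. With each cell named by its highest marker sum without clustering, the shares were 12.2% for T cell-like, 3.64% for B cell-like, 5.42% for NK cell-like, 1.56% for dendritic cell-like and 27.9% for hepatocyte-like cells. With at least 600 UMIs per cell 10.2% were dendritic cell-like, 1.05% hepatocyte-like and none neutrophil-like, and at a higher resolution 7.17% were Kupffer cell-like with 9.03% unnamed, so the shares of these classes depend on the method. A class of 17 cells with Ccl22, Il12b and Ccr7 was left unnamed, since its closest list by the rule, cholangiocyte, had 0 markers 2-fold higher in it. Ccr7 is on the fixed dendritic cell list.

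The wells fell into a lower and an upper range of well numbers, with 1526 and 1166 of these cells. T cell-like cells made up 30% of the lower range (interval 27.7 to 32.4) and 18.1% of the upper (interval 15.9 to 20.4). Dendritic cell-like cells made up 3.60% and 7.80%, plasmacytoid dendritic cell-like cells 2.42% and 6.26%, and endothelial-like cells 32.2% and 30.5%. Whether the ranges correspond to mice is not known.

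**Figure D4:**
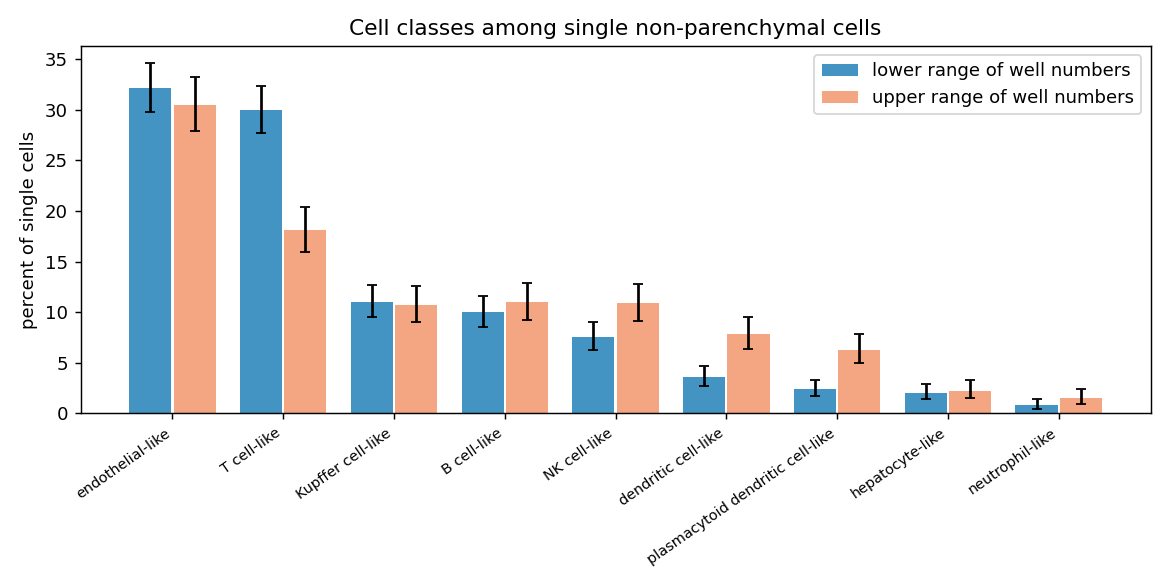
Percent of single cells in each named class (vertical axis, from 0) in the lower and the upper range of well numbers, with exact 95% binomial intervals as error bars. T cell-like cells make up 30% of the lower and 18.1% of the upper range, while the intervals of the endothelial-like class overlap.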

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

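No test in this part was chosen after the result it measures was seen. Alb, which encodes albumin and is made by hepatocytes, had a UMI in 78.3% of T cell-like cells, 81.1% of B cell-like cells and 82.6% of NK cell-like cells. These values were singled out because immune cells should lack the transcript and no comparison used it, while a count of 0 in each class would have allowed a UMI in up to 0.448%, 1.07% and 1.24% of cells at these depths, which is no limit on the share that express the gene. With each cell thinned to 300 UMIs the shares were 49.9%, 61.6% and 58.7%, beside 71.9% of endothelial-like and 100% of hepatocyte-like cells.

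Free RNA of lysed hepatocytes is a candidate source: in 8 classes the ratio of 5 other hepatocyte transcripts to Alb differed from that in pairs by a median absolute log2 difference of 0.21, where a value above 1 would have argued against it. Hepatocytes attached to a few sorted cells would put most Alb UMIs in few wells. The tenth of the endothelial-like cells with the most Alb held 34.9% of them, below the 50% set beforehand as the limit for this source. This argues against it as the main source in endothelial-like cells, but a part from it stays open. The share was not computed in T, B or NK cell-like cells, so it decides nothing for them. The shares of thinned cells differed between T cell-like (interval 46.1 to 53.8) and endothelial-like cells (interval 68.7 to 74.9). Median depths were 825 and 573 UMIs, and thinning removes more of the free RNA of a well in deeper cells. Free RNA shared evenly between wells could therefore give a difference in this direction after thinning, but none without thinning. Without thinning, Alb had a UMI in 78.3% of T cell-like (upper limit 81.4%) and 88.3% of endothelial-like cells (lower limit 86.0%). Kupffer cell-like cells, with a median depth of 887 UMIs, had a share of 73.7% after thinning (interval 68.3 to 78.7). These values argue against evenly shared free RNA as the whole cause of the difference. Free RNA shared unevenly between wells was not tested and stays open. Without thinning, Alb UMIs per cell ranged from 2.60 in T cell-like to 6.08 in Kupffer cell-like cells among the 8 classes. A further source in some classes was not tested and stays open. No biological explanation was tested.

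The 10 pericentral endothelial genes named from pairs could instead be transcripts of the pericentral hepatocyte. Their UMIs per 1000000 in pericentral pairs with more other endothelial UMIs were 2.14 times those in pairs with fewer (interval 1.99 to 2.31). The ratio was 2.32 for the other endothelial UMIs and 0.863 for the 10 named pericentral hepatocyte genes. The endothelial rule had already required that, by estimate, at least 50% of each gene's level in pairs came from endothelial RNA. A ratio above 1 was therefore likely from the outset, and a part from the hepatocyte stays open. With zones taken within well-number blocks the median log2 ratio of the 10 pericentral endothelial genes was 1.20, against 1.40 pooled, which argues against block differences as the whole cause. Expression by the endothelial cell of the pair remains a hypothesis, found and tested on the same data, and no group of samples tests it.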

How the results depend on the processing

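The alternatives without pairs with Kupffer cell markers other than Slc40a1, without blocks 1 and 2, with at least 5000 UMIs per pair, and by range of well numbers were chosen after seeing the data. Of 1082 values under an alternative, 873 stayed within the interval of the value they vary, 207 lay outside it with no called sign turned, and 2 turned. In every alternative run, each gene named from the pairs that had a value kept its direction. The extracellular matrix median of -0.26 turned to 0.01 with each pair thinned to 1000 UMIs and the cause was not tested. The Kupffer cell median of -0.72 turned to 0.13 without pairs holding at least 2 UMIs of Kupffer cell markers other than Slc40a1, a filter that removes the list's own transcripts by construction. Depth limits endothelial genes, with a median of 44.0 endothelial UMIs per pericentral pair. Not run for want of a map to mice were the edgeR and DESeq2 tests, the model with no replicate block and leaving out each mouse. Zone limits were already shared by all mice, and minimums of 500 and 2000 UMIs per pair removed no pair.

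Values that lay outside the interval follow by setting, as medians of log2 ratios per list. With pairs split at the median score, medians were Wnt targets 1.70, xenobiotic 0.59, bile acid 0.34, urea cycle -0.41, gluconeogenesis -0.16, fatty acid oxidation 0.25, lipogenesis -0.12, cholesterol -0.10, plasma proteins -0.30, complement -0.22, proteasome 0.35, Wnt ligands 0.89, haemostasis 0.18 and extracellular matrix -0.06. With the outer 20% of pairs on each side, medians were Wnt targets 3.21, xenobiotic 1.09, bile acid 0.51, urea cycle -0.78, gluconeogenesis -0.30, fatty acid oxidation 0.40, lipogenesis -0.21, plasma proteins -0.50, proteasome 0.57 and Wnt ligands 1.96. With a linear trend over 5 layers, medians were Wnt targets 2.77, xenobiotic 0.96, urea cycle -0.66, gluconeogenesis -0.26, fatty acid oxidation 0.41, plasma proteins -0.49, complement -0.36 and proteasome 0.57. With median-of-ratios size factors, medians were xenobiotic 0.70, bile acid 0.32, urea cycle -0.67, gluconeogenesis -0.30, fatty acid oxidation 0.24, lipogenesis -0.27, plasma proteins -0.51, complement -0.40, oxidative phosphorylation -0.09, proteasome 0.38 and iron and hepcidin -0.46. With each pair thinned to 1000 UMIs, medians were xenobiotic 0.76, urea cycle -0.50, gluconeogenesis -0.05, glycolysis -0.00, lipogenesis -0.09, cholesterol -0.07, plasma proteins -0.38, heme 0.90, proteasome 0.38, Wnt ligands 1.04, scavenger receptors -0.28, angiocrine 0.17, leukocyte adhesion 0.50, extracellular matrix 0.01 and dissociation -0.12. With 3 landmarks per end, medians were xenobiotic 0.76, urea cycle -0.54, fatty acid oxidation 0.29, lipogenesis -0.10 and complement -0.22. With zones within blocks, medians were xenobiotic 0.87, urea cycle -0.53, fatty acid oxidation 0.30, lipogenesis -0.12, plasma proteins -0.39, proteasome 0.40 and iron and hepcidin -0.17. Without pairs with at least 2 UMIs of Kupffer cell markers, medians were urea cycle -0.62, lipogenesis -0.22, plasma proteins -0.43 and haemostasis 0.19. With at least 100 UMIs per gene, medians were Wnt targets 1.47, heme 0.93 and Wnt ligands 2.20. With no filter on low counts, medians were haemostasis 0.83 and dissociation 0.27. With at least 80% from endothelial cells, medians were Notch and ephrin -1.02, haemostasis 1.0 and extracellular matrix -0.44. With an endothelial-like level at least 5 times the hepatocyte-like level, medians were scavenger receptors -0.17, VEGF receptors -0.09, angiocrine -0.62, leukocyte adhesion -0.30 and extracellular matrix -0.56. With all genes as library size, medians were scavenger receptors -0.23, VEGF receptors -0.05, leukocyte adhesion -0.20 and extracellular matrix -0.46.

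With at least 600 UMIs per cell the shares were 24.0% for endothelial-like, 28.0% for T cell-like, 10.4% for NK cell-like, 10.2% for dendritic cell-like, 1.05% for hepatocyte-like and 0% for neutrophil-like cells. With each cell named by its highest marker sum without clustering, they were 12.2% for T cell-like, 3.64% for B cell-like, 5.42% for NK cell-like, 1.56% for dendritic cell-like, 3.16% for plasmacytoid dendritic cell-like and 27.9% for hepatocyte-like cells. At a higher resolution they were 28.3% for endothelial-like, 22.6% for T cell-like, 7.17% for Kupffer cell-like and 1.0% for hepatocyte-like cells, while cells in clusters left unnamed made up 9.03% against 0.632%, and at a lower resolution 1.15% for hepatocyte-like cells. The same-sign share of single endothelial cells ranged from 57.6% to 67.2% over its alternatives. For all these values other than the Kupffer cell median, the cause was not tested.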

Other observations

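Of the tests in this part, those of UMIs per pair, within well-number blocks, without Nkd1 and beside Cdh13, Thbd or Fabp4 were chosen only after first values of their pattern were seen, as was leaving out Tubb5. Some genes peaked between the zones. With pairs in 5 layers of near-equal size from pericentral to periportal, Hamp2 had 1589, 4561, 6229, 4925 and 2774 UMIs and Hamp, the hepcidin gene, 2522, 5810, 7110, 7789 and 4171. Cyclin D1 (Ccnd1), which drives entry into the cell cycle, had 247, 515, 769, 812 and 481 UMIs, and Mcm6, part of the replicative helicase, 45, 63, 115, 66 and 50. Among endothelial genes Hspg2, which encodes the basement membrane protein perlecan, had 65, 143, 182, 149 and 114 UMIs, and Lyve1 240, 495, 670, 676 and 521. These genes were picked by their values from 8202 genes.

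Ccnd1, Mcm3, Mcm6 and Smc2, picked for their peak, together had a log2 ratio of the middle layer to the higher end layer of 0.73, and of 0.52 within well-number blocks, which describes that choice. The cycling cell list fixed before the data were examined had 0.30 (interval 0.14 to 0.46), which argues against a choice of genes from many as the whole cause, and 0.84 (interval 0.54 to 1.16) without Tubb5, which held 471 of its 718 UMIs in the middle layer. Pairs of the middle layer were not deeper than those of layer 1, the higher end layer for this list. The log2 ratio of median UMIs was -0.06 (bootstrap interval over pairs -0.15 to 0.06). Levels were already per UMI, so this comparison of depths does not test whether depth affects the ratio. With each pair thinned to 2000 UMIs the list had 0.20 (interval -0.20 to 0.60), which leaves depth open for the whole list. Without Tubb5 the thinned list had 0.85 (interval 0.11 to 1.62). With layers taken within well-number blocks the list had 0.09 (interval -0.08 to 0.26), and 0.51 (interval 0.18 to 0.83) without Tubb5. Differences between blocks could account for the value of the whole list and stay open, since that interval includes 0, and no biological cause is put forward.

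A coupling of Wnt target genes in the pair to the attached endothelial cell was tested at matched score in the most pericentral layers 1 and 2. The 8 target genes were 1.25 times as high in 366 pairs with a UMI of Wnt2, Wnt9b or Rspo3 as in 1479 without (interval 1.14 to 1.38), which local signalling could give. Without Nkd1, a target that also met the endothelial rule, the ratio was 1.24 (interval 1.12 to 1.37), so endothelial RNA counted through Nkd1 does not account for it. The ratio was 1.19 (interval 1.09 to 1.30) beside a UMI of Cdh13, Thbd or Fabp4, pericentral genes that are no Wnt ligands, and 1.07 (interval 0.977 to 1.18) beside Kdr or Eng. Position within the zone that the score does not resolve may therefore account for the first ratio, and local coupling and position cannot be told apart.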
